A study of Mus musculus with 2 samples.

How the data were processed

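Dimethylation of histone H3 at lysine 4 (H3K4me2), a mark of promoters and of distal regulatory regions, was profiled by chromatin immunoprecipitation and sequencing in neural tube dissected from mouse embryos of both sexes at embryonic day 14.5. The study had 1 group of 2 libraries. Per the labels they were biological replicates, replicate 1 made from tissue of 24 embryos and replicate 2 from tissue of 34 embryos, so the replicates came from separate pools of animals. The control library named in the labels was not used here.

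The deposited data were 4 peak lists on the mm10 build, per the file headers: 1 list called on each replicate, 1 list called on both replicates pooled, and 1 list of pooled peaks kept as replicated. The accompanying text files, per the labels, derived the replicated list from the pooled list and both replicate lists, and named 1 further input file for the list of replicate 1 and 2 for that of replicate 2, without saying what these files held. The aligner, the peak caller, its threshold and the rule for keeping a replicated peak were not given in the sources used here. The fold enrichment of each peak is a ratio computed by the authors, and its score is the authors' own scaled value. The -log10 p-value and -log10 q-value of each peak were also computed by the authors, and the smallest -log10 p in the deposited lists was 2.02 in replicate 1 and 2.14 in replicate 2. These peak values were used only within a list, to describe, rank, filter or compare its peaks. The files gave no read counts, so the depth of the libraries is unknown and limits the weaker peaks by an amount that could not be measured.

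Genes and starts were taken from GENCODE M21 (GRCm38, the assembly of mm10), with sequence from the RefSeq copy of the same assembly. After 27 repeated symbols were dropped, 21911 protein-coding genes on the placed chromosomes were kept, and the start of a gene was its annotated 5' end. A promoter was marked where a peak overlapped the 5' end extended by 1 kb on each side. A peak was distal when its nearer edge lay over 5 kb from every such 5' end, and it was assigned to the gene with the 5' end nearest to its centre. Covered length was the number of bases under replicated peaks within 5 kb on each side of the 5' end, a window of 10001 bp. Peaks that touched a promoter were classed first, then those touching an exon, then those inside a protein-coding gene, and the rest were intergenic. Genes of other types and further annotated starts were not used for these classes. Intergenic and distal peaks may therefore include peaks at such genes or starts.

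Peaks of the replicates were called shared when the overlap reached 50% of the length of either peak. Observed overlaps, locations and CpG contents were compared with 100 circular shifts of the peaks within each chromosome, leaving out the first 3 Mb, which gives a smallest one-sided p of 0.0099. The 21 gene lists, holding 346 chosen genes and the olfactory receptor family with no gene in more than 1 list, were fixed before the data were examined, as were the main alternatives and the tests, apart from those of pairs of lists and of X-linked promoters, which were added later. The share of marked promoters in each list was compared with all other protein-coding genes by a two-sided Fisher's exact test, with Benjamini-Hochberg adjustment over the 21 lists and exact 95% binomial intervals. The median covered length and the mean number of distal peaks of each list's marked genes were compared with 100000 random draws of as many marked genes, a two-sided permutation test adjusted over the 17 lists with at least 3 marked members, whose smallest p is 2e-05. Widths and folds of promoter and distal peaks were compared by a two-sided permutation test of the absolute difference of the medians with 100000 resamples, whose smallest p is 1e-05. Genes and peaks are not independent replicates, so these p-values describe lists and peaks within this tissue, not variation between animals. Values given as mean ± SD are over the 2 replicates.

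The genes named were chosen by a rule fixed before the data were examined: the 20 genes with the greatest covered length, with ties in order of symbol, the 2 members with the greatest covered length and the first 2 unmarked members in alphabetical order of each list, the genes nearest the 5 strongest peaks, the 5 strongest promoters marked in 1 replicate alone for each replicate, the 5 genes with the most distal peaks, all Hox genes, and further list members as examples. Rates of 6-base words were compared between distal peaks and flanks of the same width 2 kb away on each side that held no pooled peak, with jackknife standard errors over 21 chromosomes.

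The computations were done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and numba 0.67.0, and figures were drawn with matplotlib 3.10.9. The procedures were tested on simulated data. With 59.4% of 33019 peaks left in place and the rest moved, the overlap procedure called 59.8% shared. Of 20 simulated lists with a raised share of marked promoters among the 21911 genes, the promoter test called 13, and it called 0 of 80 unchanged lists. Most of the real lists held fewer genes than the simulated ones. A real list that did not pass may therefore still differ from other genes. Among 13674 genes, the covered-length test called 10 of 10 lists raised 2-fold and 1 of 30 unchanged lists, and the distal-peak test called 6 of 10 lists raised 4-fold and 0 of 30 unchanged lists.

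Alternatives were an overlap of 1 bp or of 50% of both peaks, the upper 50% of a list by fold, lists of equal length, merged peaks, promoter windows of 500 bp or 2.5 kb, any annotated transcript start of the gene, a covered-length window of 10 kb on each side, a distal distance of 2.5 kb, distal peaks per 100 kb of the gene's territory, the pooled list, and the list of each replicate in place of the replicated list. For covered length and distal peaks, each alternative peak list defined its own marked genes, so the genes compared could change as well as their values. After the data had been seen, a q limit of 0.05 on the replicated list and a restriction to replicated peaks that overlapped both replicate lists were added. The 11 replicated peaks on scaffolds outside the placed chromosomes entered no comparison with genes.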

Results

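The H3K4me2 landscape of the embryonic mouse neural tube, the tissue that forms the brain and spinal cord, was measured in 2 biological replicates at embryonic day 14.5. Replicate 1 gave 43046 peaks covering 38.9 Mb and replicate 2 gave 50985 peaks covering 51.2 Mb, a mean of 45.0 ± 8.73 Mb (SD, n = 2). The pooled list held 42216 peaks over 48.6 Mb. The replicated list, used for the comparisons unless another list is named, held 33030 peaks over 46.2 Mb, or 1.70% of the genome, with a median width of 1033 bp. The read depth of the libraries is unknown because the peak lists give no counts.

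Almost all strong H3K4me2 peaks occurred in both embryo pools, and the peaks seen in 1 pool alone were weak. In replicate 1, 81.5% of peaks (95% Wilson interval 81.1% to 81.8%) overlapped a peak of replicate 2, against a mean of 2.81% after circular shifts. In replicate 2, 56.8% of peaks (56.4% to 57.3%) overlapped a peak of replicate 1, against 2.32% after shifts. Both overlaps exceeded every shift (shift permutation p = 0.0099, the smallest the shifts allow). The lists shared 36.0 Mb, which was 92.6% of the bases covered in replicate 1 and 70.3% of those covered in replicate 2, and a Jaccard index of 0.666 against 0.00935 in shifted lists (shift permutation p = 0.0099). With 1.32 times as many covered bases, replicate 2 contained most of replicate 1.

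Ranked by the authors' own fold within each list, the strongest 20% of peaks were shared at 100% in both replicates. Among the weakest 20%, 43.9% of replicate 1 peaks (42.9% to 45.0%) and 8.71% of replicate 2 peaks (8.18% to 9.27%) were shared. All 33030 replicated peaks were pooled peaks. They included each of the 28650 pooled peaks that overlapped both replicate lists, and 4380 others, 13.3% of the list, with a median fold of 3.67. The 9186 pooled peaks left out had a median fold of 3.01, against 10.98 for the replicated ones, and 7000 of them overlapped a peak of replicate 2 alone, 1029 of replicate 1 alone and 1157 of neither.

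**Figure D1:**
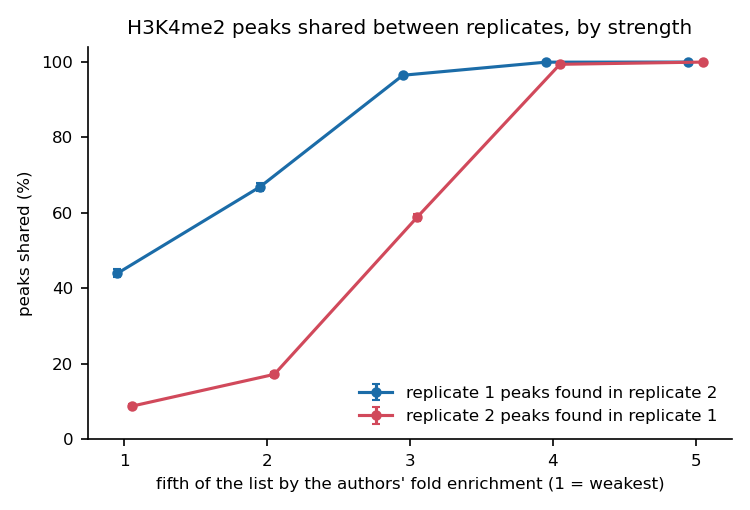
Share of H3K4me2 peaks (%, with 95% Wilson intervals) found in the other replicate, in 5 equal classes of each replicate's list ranked on the authors' fold enrichment. Sharing reached 100% among the strongest peaks of both replicates and was 43.9% for replicate 1 and 8.71% for replicate 2 among the weakest.

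H3K4me2 peaks at gene promoters were wider and stronger than those over 5 kb from the annotated 5' end of every protein-coding gene. Of the replicated peaks on placed chromosomes, 15092 (45.7%) touched a promoter, 16.0 times the mean of 2.85% after circular shifts. A further 4120 peaks (12.5%, against 10.1% shifted) touched an exon, 6313 (19.1%, against 30.2%) lay in introns and 7494 (22.7%, against 56.9%) were intergenic. Each share lay outside the range of the 100 shifts (shift permutation p = 0.0099). Promoter peaks had a median width of 1705 bp and a median fold of 19.1, whereas the 13887 distal peaks had a median width of 652 bp and a median fold of 5.36 (permutation p = 1e-05 for both, the smallest the resamples allow). Promoter peaks made up 6.80% of the weakest 20% of replicated peaks and 83.2% of the strongest, while distal peaks made up 69.3% and 12.8% of them.

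The peaks with the highest fold were mostly promoters. The strongest, at 48.1-fold, covered chromosome 7 from 48880387 to 48882686 at the 5' end of E2f8, a transcriptional regulator of the cell cycle. The next covered chromosome 13 from 35967576 to 35970013 at 46.5-fold, touching an exon 8737 bp from the nearest protein-coding 5' end, that of Ppp1r3g. Peaks at the 5' ends of Col27a1 (46.3-fold), Abr (45.7-fold) and Adgrg6 (44.9-fold) followed. Sequence under the peaks was rich in CpG dinucleotides. The median CpG observed/expected ratio was 0.580 in promoter peaks, against 0.164 when these peaks were shifted, and 0.405 in distal peaks, against 0.159 (shift permutation p = 0.0099 for both), and the median GC content was 53.3% and 50.6%, against 41.7% in either set of shifted peaks.

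H3K4me2 marked 13674 of 21911 protein-coding promoters, or 62.4% (95% Wilson interval 61.8% to 63.0%). The replicates marked 13611 and 13954 promoters, a mean of 62.9 ± 1.11% (SD, n = 2), and 13548 promoters were marked in both. In replicate 1 alone 63 promoters were marked, the strongest at Acsl5 (21.7-fold), F10 (4.05-fold), Gm3411, Olfr222 and Tagap1 (3.99-fold each). In replicate 2 alone 406 were marked, the strongest at Chrm1 and Meig1 (31.3-fold each), E130218I03Rik (30.7-fold), Hrc (27.8-fold) and Pomgnt2 (27.6-fold). At Acsl5 and at all 5 of these replicate 2 genes both replicates had covered bases within 5 kb of the 5' end, for example 1172 ± 181 bp (SD, n = 2) at Chrm1 and 3212 ± 709 bp at Hrc.

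The gene lists asked which programmes carried the mark at their promoters. Marked promoters were more frequent than in other genes for pan-neuronal differentiation genes, Hox genes, dorsoventral progenitor domain factors, neural progenitor and radial glia genes, cell cycle genes and housekeeping genes. They were less frequent for liver, gut, lung and pancreas differentiation genes, germline and meiosis genes, epidermal genes, blood and microglia genes, developmental factors of other lineages, and olfactory receptors. The other 9 of the 21 lists did not pass the test.

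All 20 pan-neuronal genes were marked (100%, exact 95% interval 83.2% to 100%, adjusted Fisher's exact p = 4.1e-04), including the tubulin gene Tubb2b and the RNA-binding protein gene Celf4. Of the 22 dorsoventral factors, which divide the neural tube into progenitor domains, 21 were marked (95.5%, adjusted exact p = 0.00217), with Irx3 at 23.5-fold and Ascl1 at 27.2-fold and Dbx1 unmarked. Restricted to the upper 50% of replicated peaks by fold, 45.5% of the dorsoventral promoters were marked, below other genes (adjusted exact p = 0.457), and the progenitor list lost its call at 68.8% (adjusted exact p = 0.493). In the full replicated list, 15 of 16 progenitor genes were marked (93.8%, adjusted exact p = 0.0145), among them Sox2, Pax6, Nes, Zic1 and the Notch ligand gene Dll1. The exception, Notch1, was marked at another annotated start. Marks were found at all 12 cell cycle promoters (adjusted exact p = 0.0107), with Mcm2 at 24.5-fold and Aurkb at 29.8-fold, and at 15 of 16 housekeeping promoters (adjusted exact p = 0.0145), with Ywhaz marked only at another start. Among 39 Hox promoters 38 were marked (97.4%, adjusted exact p = 2.5e-06).

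Promoters in the lists of other organs and lineages, of the germline, of olfactory receptors, and of blood and microglia were mostly unmarked. None of the 19 liver, gut, lung and pancreas genes was marked (0%, exact 95% interval up to 17.6%, adjusted Fisher's exact p = 8.8e-08), including Alb and Afp. Only Dazl was marked among 13 germline genes (adjusted exact p = 3.5e-04), Lor among 10 epidermal genes (adjusted exact p = 0.00297, and 0.0624 at 30.0% with a promoter window of 2.5 kb), and Olfr1033 and Olfr658 among 1134 olfactory receptors. Of 16 blood and microglia genes 4 were marked (25%, adjusted exact p = 0.00743), namely Gypa, Klf1, Epor and P2ry12, while Aif1 and Alas2 were not. Among 25 developmental factors of other lineages 8 were marked (32.0%, adjusted exact p = 0.00743), including Gata6 at 11.5-fold and Tbx1 at 4.76-fold, while Cdx2 and Foxn1 were not. Skeletal muscle structural genes were marked at 4 of 12 promoters (33.3%, adjusted exact p = 0.102), and the list passed the test when any annotated start counted (adjusted exact p = 0.0474). Of those 4, Ckm, Mylpf and Actn3 each had the start of another protein-coding gene within 2 kb.

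Neuronal and glial lists that did not pass the test fell on both sides of the share in other genes. Postmitotic spinal neuron factors were marked at 23 of 31 promoters (74.2%, adjusted exact p = 0.260), with Lhx1 and Lmx1b marked and Barhl1 and Evx1 unmarked, and 3 of the 8 unmarked genes were marked at another start. The list passed the test with a promoter window of 2.5 kb (87.1%, adjusted exact p = 0.0146), in the pooled list (83.9%, adjusted exact p = 0.0248) and in the list of replicate 2 (87.1%, adjusted exact p = 0.0146). Neurotransmitter genes were marked at 13 of 18 promoters (72.2%), with the inhibitory transporter genes Slc32a1 and Slc6a5 marked and Dbh and Gabrb3 unmarked, the latter marked at another start. Neural crest and peripheral neuron genes were marked at 9 of 12 (75%), with Foxd3 and Ret marked and Phox2b and Runx3 unmarked, the latter marked at another start. Forebrain and midbrain factors were marked at 11 of 19 (57.9%), with En2 at 15.5-fold and Fezf2 and Foxg1 unmarked, and Foxg1 was marked at another start. In the upper 50% of peaks by fold the forebrain and midbrain share was 21.1%, below other genes (adjusted exact p = 0.00620), and it lay above other genes without passing the test at 68.4% in the pooled list and with a 2.5 kb window. Early glial genes were marked at 9 of 11 (81.8%), including Slc1a2 and Nfia but neither Aldh1l1, which was marked at another start, nor S100b. Mature glial genes were marked at 3 of 10 (30.0%, adjusted exact p = 0.0773), namely Mbp, Cldn11 and Gjb6, while Gfap and Aqp4 were not. Vascular and mesenchymal genes were marked at 10 of 16 (62.5%), with Pdgfrb and Foxc1 marked and Cdh5 and Col3a1 unmarked, and pluripotency genes at 3 of 9 (33.3%), namely Klf4, Lin28a and Tdgf1, with Dppa3 and Dppa5a unmarked.

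Comparisons between pairs of lists were chosen after the values had been seen. Their p-values were adjusted over the 5 chosen pairs alone, which does not allow for the choice, so they are likely too small. The dorsoventral list had a higher marked share than the forebrain and midbrain list (21 of 22 against 11 of 19, adjusted Fisher's exact p = 0.00804 over 5 pairs) and than the factors of other lineages (8 of 25, adjusted exact p = 5.2e-05). Hox genes exceeded forebrain and midbrain factors (38 of 39 against 11 of 19, adjusted exact p = 4.8e-04). The pan-neuronal list exceeded the mature glial list (20 of 20 against 3 of 10, adjusted exact p = 1.5e-04), and the early glial list did so as well (9 of 11 against 3 of 10, adjusted exact p = 0.0300). The difference between the dorsoventral and the forebrain and midbrain lists did not pass when any annotated start counted (adjusted exact p = 0.0795), in the upper 50% of peaks by fold (adjusted exact p = 0.232) or in replicated peaks overlapping both replicate lists (adjusted exact p = 0.0753), and that between the glial lists did not pass in the upper 50% of peaks (adjusted exact p = 0.659).

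**Figure D2:**
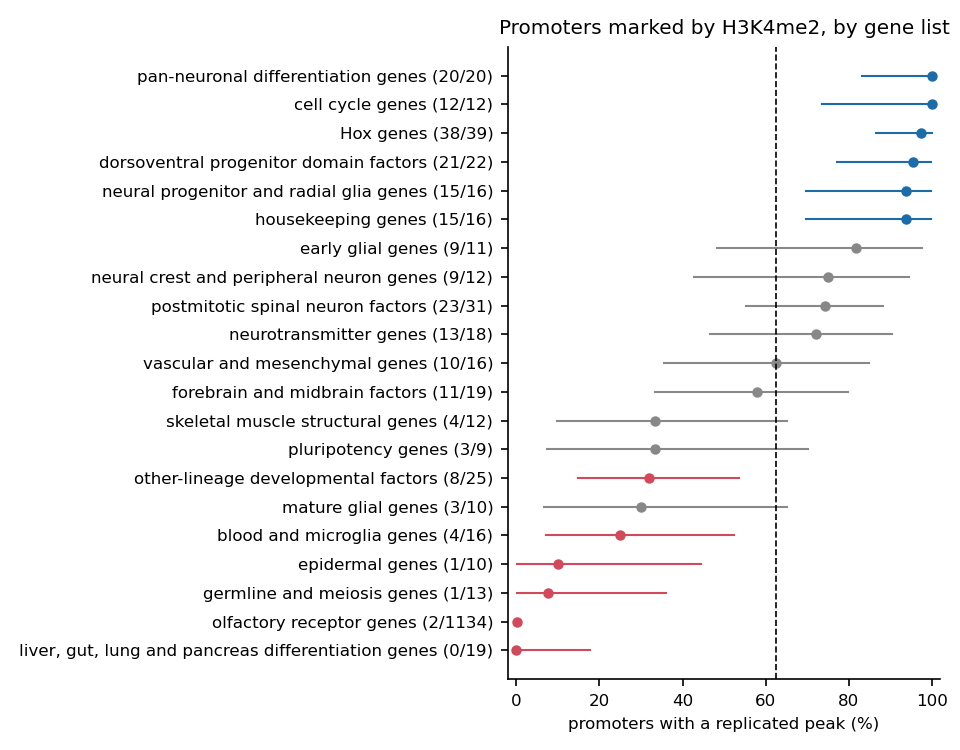
Share of promoters with a replicated H3K4me2 peak (%) in each of 21 gene lists, with exact 95% binomial intervals; marked and total members stand in brackets and the dashed line is the share of all protein-coding genes (62.4%). Blue lists lay above and red lists below other genes in the adjusted Fisher's exact test, and grey lists did not pass it.

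Covered length described how many bases within 5 kb of the 5' end lay under any peak, including separate peaks and those at neighbouring genes. It is not the width of the promoter peak: Foxd3 had 5564 bp covered, with a strongest promoter peak of 830 bp. Marked Hox genes, neural progenitor genes, postmitotic spinal neuron factors and pan-neuronal genes had longer H3K4me2 coverage than random marked genes, and forebrain and midbrain factors and factors of other lineages had shorter coverage. Within the 10001 bp window, the median was 9761.5 bp for 38 Hox genes, 5356 bp for 15 progenitor genes, 5044 bp for 23 spinal neuron factors and 5024.5 bp for 20 pan-neuronal genes, against about 2410 bp in random draws (adjusted permutation p = 8.5e-05 for each). The draws took the 38 Hox genes as separate, although neighbouring Hox genes share peaks, so the p-value for Hox genes is likely too small. All 15 progenitor genes and 19 of the 20 pan-neuronal genes lay above the median of marked genes, as did 15 of the 23 spinal neuron factors. Over the replicates the medians were 9203.5 ± 855 bp for Hox genes, 5034 ± 594 bp for progenitor genes, 4418.5 ± 1012 bp for spinal neuron factors and 4550.5 ± 751 bp for pan-neuronal genes (SD, n = 2).

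Coverage was short at marked forebrain and midbrain factors and at marked factors of other lineages. The 11 forebrain and midbrain factors had a median of 1438 bp (adjusted permutation p = 0.0117), with 2311 bp at Eomes and 2004 bp at En2, and none of the 11 lay above the median of marked genes. The 8 marked factors of other lineages had a median of 1161 bp (adjusted permutation p = 0.00326). The forebrain and midbrain call did not pass with a window of 10 kb on each side (adjusted permutation p = 0.05) or in the upper 50% of peaks by fold (adjusted permutation p = 0.133), where the call for factors of other lineages did not pass either (adjusted permutation p = 0.0529). The upper 50% of peaks marked only 4 forebrain and midbrain factors, 3 factors of other lineages and 5 early glial genes. Values there rest on these smaller sets of genes. The 21 dorsoventral factors had a median of 2372 bp (adjusted permutation p = 0.913). The early glial list, at 3198 bp (adjusted permutation p = 0.260), passed the test at 4791 bp in the list of replicate 2 (adjusted permutation p = 0.00432), at 4098 bp in the pooled list (adjusted permutation p = 0.0294) and at 5397 bp in the upper 50% of peaks (adjusted permutation p = 0.00432), and lay below random genes at 1628 bp in the list of replicate 1 (adjusted permutation p = 0.343). Housekeeping genes, at 3417 bp (adjusted permutation p = 0.0552), passed with a window of 10 kb on each side (adjusted permutation p = 0.0440), and they and the blood and microglia genes, at 1292.5 bp (adjusted permutation p = 0.0552), passed in replicated peaks overlapping both replicate lists (adjusted permutation p = 0.0478 and 0.0496). Mature glial genes, at 1376 bp (adjusted permutation p = 0.175), passed below random genes in the upper 50% of peaks (adjusted permutation p = 0.0494).

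A total of 23 genes had the whole window covered, and 14 of these were Hox genes. Many of these Hox genes share a peak, with Hoxb3 to Hoxb8 in a peak of 79436 bp and Hoxa3, Hoxa6 and Hoxa7 in a peak of 28497 bp. They are therefore not separate measurements. The first 20 of these in order of symbol, which the naming rule takes, were Hoxa3, Hoxa6, Hoxa7, Hoxb3 to Hoxb8, Hoxc5, Hoxc6, Hoxc9, Hoxd3, Hoxd4, Gm28308, whose annotated 5' end lies within 2 kb of that of Hoxa3, and, outside the Hox clusters, Bahcc1, Basp1, Bcl11a, Ebf3 and Lhx1. In these 5 the replicates covered 9656 ± 488 bp at Bahcc1, 9702.5 ± 422 bp at Basp1, a growth cone protein gene, 9859 ± 107 bp at Bcl11a, 9982 ± 26.9 bp at Ebf3 and 9603.5 ± 501 bp at Lhx1 (SD, n = 2). The other 3 were Meis2, Pou3f3 and Sall3, named after their values were seen. Bcl11a, Ebf3 and Lhx1 encode transcription factors. The spinal neuron factor genes Lmx1b (9896 bp), Lhx5 (9309 bp), Tlx3 (9142 bp), Lbx1 (8940 bp) and Pax2 (8565 bp) and the vesicular inhibitory transporter gene Slc32a1 (9756 bp) were also almost wholly covered, as was the progenitor gene Zic1 (9799 bp).

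Distal H3K4me2 peaks were more numerous around 5 of the 17 lists tested than around random marked genes. Marked progenitor genes had a mean of 5.67 distal peaks each, postmitotic spinal neuron factors 4.70, early glial genes 3.89, pan-neuronal genes 3.6 and dorsoventral factors 3.48, against a median of 0.667 to 0.739 in random draws of marked genes (adjusted permutation p = 1.1e-04, 1.1e-04, 0.0101, 1.1e-04 and 1.7e-04). Averaged over the lists of the 2 replicates, the means were 8.5 ± 1.18, 7.67 ± 2.37, 6.28 ± 1.34, 5.5 ± 1.27 and 4.88 ± 2.12 in the same order (SD, n = 2). No list passed the test below random genes. Sox2 had 19 distal peaks, Pax2 and Foxp1 16 each, Lmx1b and Sox9 13 each, Nfib 12 and Zic1 and Celf4 11 each. Of the marked dorsoventral factors 20 of 21 had at least 1 distal peak, with 8 each at Pax3, Irx3 and Nkx6-1. Forebrain and midbrain factors had 2 each (adjusted permutation p = 0.206), and neurotransmitter genes (0.846), neural crest and peripheral neuron genes (0.778) and mature glial genes (0.333) did not pass either (adjusted permutation p = 1 for each). Hox genes had 1.05 each (adjusted permutation p = 0.732), cell cycle genes 1.00 and housekeeping genes 1.07. Counted per 100 kb of territory, which allows for the spacing of genes, the dorsoventral call (adjusted permutation p = 0.0688) and the pan-neuronal call (adjusted permutation p = 0.0551) did not pass, whereas Hox genes (adjusted permutation p = 6.8e-04) and housekeeping genes (adjusted permutation p = 0.0495) did. The early glial call was lost in the upper 50% of peaks by fold, at 0.6 peaks per gene over the 5 genes still marked (adjusted permutation p = 0.373).

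In the replicated list the genes with the most distal peaks were Gm11146 with 34, Tcf4 with 29, Pmfbp1 with 28, and Adgrl2 and Runx1t1 with 26 each. The order depended on the list, since Zfp608 was first in the list of replicate 2 with 61, ahead of Pmfbp1 with 58, Tcf4 with 55 and Gm11146 with 49, and Pmfbp1 was first in the pooled list with 45. Tcf4, which encodes a broadly expressed partner of proneural factors, Adgrl2 and Runx1t1 were marked at the promoter, with covered lengths of 4726, 5966 and 6584 bp, whereas Gm11146 and Pmfbp1 were not marked.

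**Figure D3:**
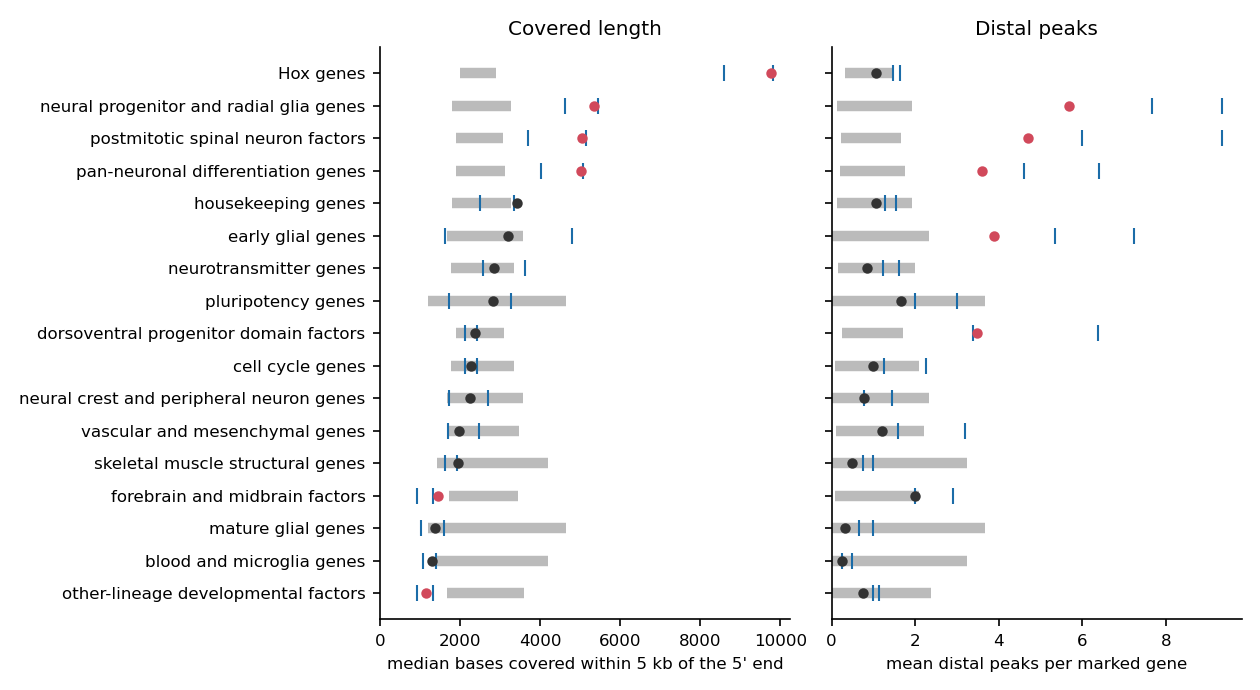
Left, median bases covered by replicated peaks within 5 kb of the 5' end of each list's marked genes; right, mean distal peaks per marked gene. Points are the replicated list (red where the adjusted permutation test passed), blue ticks the 2 replicate lists, and grey bars the central 95% of random draws; Hox genes led the left panel at 9761.5 bp and progenitor genes the right panel at 5.67 peaks.

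The Hox clusters, which encode position along the head-to-tail axis, were broadly covered by H3K4me2, and the 3 widest replicated peaks of the genome lay in Hoxb, Hoxa and Hoxc. Replicated peaks covered 74.5% of the Hoxa cluster with 5 kb on each side (chromosome 6, 52150590 to 52265880), 54.5% of Hoxb (chromosome 11, 96189316 to 96373256), 80.1% of Hoxc (chromosome 15, 102916103 to 103041852) and 65.7% of Hoxd (chromosome 2, 74663310 to 74770142). Over the replicates the shares were 70.7 ± 8.94%, 53.7 ± 2.63%, 73.5 ± 15.1% and 61.2 ± 10.6% (SD, n = 2), each higher in replicate 2. Hoxb was the lowest of the 4 in both replicates, by less than the spread between replicates against Hoxd. Its interval, the longest of the 4 at 184 kb, includes the stretch between the 5' ends of Hoxb13 (96194316) and Hoxb9 (96271457). No other listed Hox gene starts in that stretch. The share was not computed without it, so it does not rank Hoxb as the least covered around its genes. In the upper 50% of peaks by fold 46.3% of Hoxc and 51.4% of Hoxb was covered, which turned their order. The widest peak ran over 79436 bp of chromosome 11 from 96268044 to 96347479 and held the 5' ends of Hoxb9 to Hoxb3, with 78179 bp of it covered in replicate 1 and 79259 bp in replicate 2. The next widest lay over Hoxa5 to Hoxa7 (chromosome 6, 52199773 to 52228269, 28497 bp) and over Hoxc10, Hoxc5 and Hoxc9 (chromosome 15, 102962333 to 102989211, 26879 bp).

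Within the clusters the mark was broad over most genes of paralog groups 1 to 9 and short at most genes of group 13, a division not fixed beforehand and not tested. The median covered length was 10001 bp for the 27 genes of groups 1 to 9 and 6250 bp for the 12 genes of groups 10 to 13, with 9625 and 3367 bp in replicate 1 and 10001 and 7768 bp in replicate 2. Hoxa13 had 664 bp, Hoxb13 470 bp, Hoxd13 1394 bp and Hoxc13 3137 bp, the last with 2939.5 ± 2600 bp over the replicates (SD, n = 2), and Hoxd12 was the 1 Hox gene without a marked promoter. Some genes of groups 10 to 12 also differed between the replicates, with 7833.5 ± 2630 bp at Hoxc11, 6669 ± 2790 bp at Hoxa11 and 5710.5 ± 3350 bp at Hoxc12 (SD, n = 2). Hoxc10 differed less, at 9488 ± 496 bp, and genes of groups 1 to 9 could differ as well, with 5347.5 ± 2177 bp at Hoxc4 (SD, n = 2). In group 1, Hoxb1 (1479 bp) and Hoxd1 (1964 bp) were also short, while Hoxa1 had 7285 bp. The annotated 5' ends of Hoxd3 and Hoxd4, of Hoxc5 and Hoxc10, and of Hoxa3 and Gm28308 lie within 2 kb of each other. Other neighbouring Hox genes share a peak or have overlapping windows. The values of neighbouring Hox genes are therefore not separate measurements. Some annotated 5' ends are also out of paralog order. That of Hoxa3 (52213336) lies between those of Hoxa6 and Hoxa7, and that of Hoxc5 (102967443) beside that of Hoxc10 (102966796). The values of Hoxa3 and Hoxc5 thus describe the surroundings of those other genes. The group medians were not recomputed without them.

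**Figure D4:**
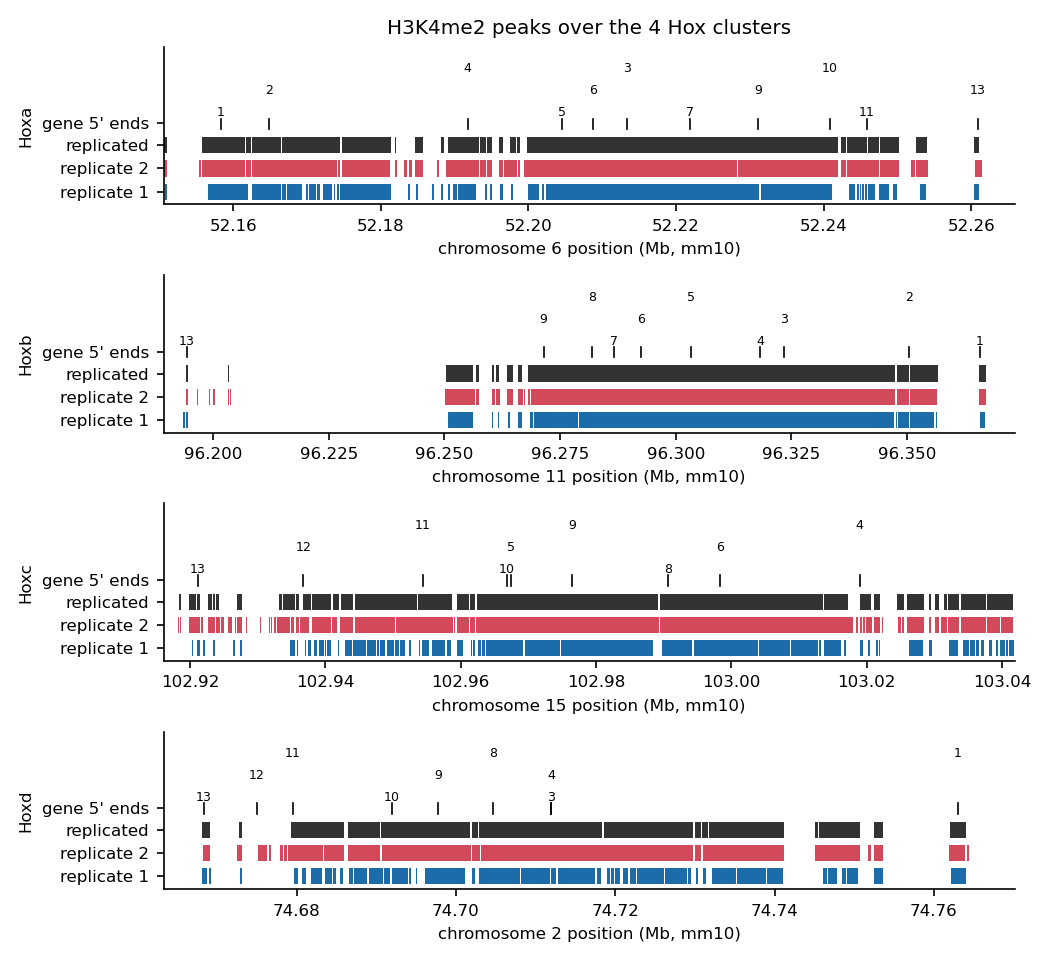
H3K4me2 peaks of replicate 1 (blue), replicate 2 (red) and the replicated list (black) over the Hoxa, Hoxb, Hoxc and Hoxd clusters in Mb of mm10, with ticks at the annotated 5' ends and numbers for paralog groups. A single replicated peak of 79436 bp spans Hoxb9 to Hoxb3, and the 5' ends of group 13 carry short peaks.

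Other wide domains lay outside the Hox clusters. A peak of 23785 bp on chromosome 13 (83712845 to 83736629) lay outside protein-coding genes. Non-coding genes were not considered, so it may lie at one of them. The nearest protein-coding 5' end, that of Mef2c, a transcription factor gene, was 208811 bp away. The peak was covered over 23361 bp in replicate 1 and 23078 bp in replicate 2. A peak of 19199 bp on chromosome 11 (24072927 to 24092125) held the 5' ends of Bcl11a and A830031A19Rik, the latter named after its values were seen.

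Peaks were sparse on the X chromosome. The autosomes carried 13 replicated peaks per Mb, from 9.42 on chromosome 14 to 20.5 on chromosome 11, and the X chromosome carried 5.73 per Mb, below every autosome. The ratio of X to autosomes was 0.440 in the replicated list and 0.4 ± 0.0432 over the replicates (SD, n = 2). Marked promoters made up 48.6% of the 948 X-linked genes and 63.6% of the 20780 autosomal genes (two-sided Fisher's exact p = 6.2e-20, a test not fixed beforehand). The gap of -14.9 points widened to -27.4 points in the upper 50% of peaks by fold. Distal peaks per Mb on the X chromosome were at 0.331 of the autosomal rate. The Y chromosome carried 4 replicated peaks. The embryo pools were of mixed sex.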

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

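All tests in this part were planned before their results were seen. The replicated list held 11 peaks on scaffolds outside the placed chromosomes, a signal in data that entered no comparison with genes. The study has 1 group, so no biological explanation was tested against the technical ones.

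Replicate 2 listed more peaks and more covered bases than replicate 1. Of its 22012 peaks without a partner in replicate 1, 94.5% lay in the lower 50% of its own list by fold, which is what weak peaks near the calling limit would give, and so did 99.8% of the 7978 unmatched peaks of replicate 1. Cells of another type in one pool remain a possible explanation for a few peaks. Among vascular and mesenchymal genes, Cdh5, Col3a1 and Tie1 were marked in replicate 2 alone, 3 of 13 (23.1%) against 2.88% of other marked genes. This met the prediction written beforehand for that explanation (smallest adjusted Fisher's exact p = 0.0278 over 5 lists). Their promoter peaks were themselves weak, with folds of 3.16, 2.85 and 3.10 against a median of 3.33 in the unmatched peaks, a comparison not planned beforehand. A few such cells could also give weak peaks, so the folds cannot decide between the explanations. Col3a1 had 547 covered bases around its start in replicate 1. The other 4 non-neural lists held only 4, 4, 0 and 1 genes marked in either replicate, too few to tell. Depth stays open, as does the control each list was called against, since neither is given in the sources used here.

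Promoters of some developmental factors of other lineages carried the mark, 8 of 25. Genes matched on promoter CpG were marked at a median of 76.0% (central 95% range 64.0% to 88.0%), above the observed 32.0% (permutation p = 2e-05). This argues against CpG-rich promoters carrying the mark whatever the lineage, and it does not exclude CpG content as a contributor at the 8 marked promoters. Cells of those lineages in the dissected tissue cannot be told apart from other sources: their differentiation genes were marked at 5 of 41 (12.2%), 19.8 points lower, with a 95% interval from -0.122 to 40.6 points and a Fisher's exact p of 0.0622. Among these 5, Ckm, Mylpf and Actn3 had the start of another protein-coding gene within 2 kb, as did Foxa3 among the 8 factors. The marks at these genes may belong to the neighbours, and the comparison was not repeated without them.

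Covered length around the Hox, neural progenitor, spinal neuron and pan-neuronal genes exceeded that of other marked genes. Neighbouring gene starts inside the window were argued against as the whole cause, since 4 of 4 lists still passed in draws matched on the number of starts. CpG-rich sequence around the start was argued against in the same way, with 4 of 4 lists passing in draws matched on CpG (largest adjusted permutation p = 0.00274). The matched medians rose to between 2567 and 3515 bp, so that CpG content may account for part of the excess, and the ratio to matched genes was 1.43 for spinal neuron factors and 3.03 for Hox genes. What sets the rest was not tested.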

How the results depend on the processing

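The q limit of 0.05, the restriction to replicated peaks overlapping both replicate lists and the alternatives of the list pairs and of X-linked promoters were chosen after the data were seen. Of 622 values recomputed under an alternative, 554 were kept. A value was kept if it held its direction and side of the threshold or moved by less than its spread. A count was kept if it stayed within a set ratio of the main value. Among 485 for gene lists, 12 lost a call and 14 gained one without changing direction, and 25 changed direction. The dorsoventral promoter share in the upper 50% of peaks both changed direction and lost its call (adjusted Fisher's exact p = 0.457). No list that passed a test passed it in the opposite direction. The cause was not tested. The gap in sharing between the strongest and weakest peaks, 56.1 points in replicate 1 and 91.3 in replicate 2, was 49.2 and 87.0 at 1 bp of overlap and 75.7 and 86.1 at 50% of both peaks, where 70.5% of replicated peaks overlapped both lists. Lists below random genes in covered length numbered 1 in place of 2 with 10 kb on each side, where the factors of other lineages passed, and 1 in the upper 50% of peaks, where both lost their call and mature glial genes passed. In that upper 50%, 60.0% of Hoxa, 51.4% of Hoxb, 46.3% of Hoxc and 52.0% of Hoxd was covered, and the X ratio was 0.329, against 0.393 in the pooled list. With 1 replicate left out, Hoxa ranged from 64.4% to 77.0%, Hoxb from 51.9% to 55.6%, Hoxc from 62.8% to 84.1%, Hoxd from 53.7% to 68.7% and the X ratio from 0.370 to 0.431.

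Changes of direction did not pass the test in the alternative. For marked promoters they were forebrain and midbrain factors at 68.4% with a 2.5 kb window and in the pooled list and 73.7% with any start, vascular genes at 62.5% with any start, and in the upper 50% of peaks dorsoventral factors at 45.5%, spinal neuron factors at 48.4%, early glial genes at 45.5%, neural crest genes at 33.3% and vascular genes at 37.5%. For covered length they were dorsoventral factors at 3399 bp and neural crest genes at 2868 bp with 10 kb on each side, neural crest genes at 2606 bp in the pooled list, and dorsoventral factors at 2615 bp in peaks overlapping both lists. With 1 replicate left out, covered length ranged from 2223 to 2414 bp for dorsoventral factors, 1751.5 to 2694 bp for neural crest genes, 1628 to 4791 bp for early glial genes, 1731 to 3273 bp for pluripotency genes and 2133 to 2433 bp for cell cycle genes. For distal peaks they were vascular genes at 0.532 and pluripotency genes at 0.240 per 100 kb of territory, neurotransmitter genes at 0.0769, Hox genes at 0.103 and vascular genes at 0 in the upper 50% of peaks, and factors of other lineages at 0.889 in the pooled list and 1 without replicate 1, with the same value without replicate 2. No paired analysis was possible because the study has a single group. The depth is unknown, so its limit on weak peaks could not be measured.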

Other observations

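Distal peaks also differed between marked and unmarked genes as a whole. Genes with a marked promoter had a mean of 0.782 distal peaks and those without had 0.388, and 6074 genes had at least 1. Several neural factor genes without a mark at the annotated 5' end had distal peaks nearest to them, with 9 at Notch1, 5 each at Otx2, Lhx4 and Sox14 and 4 at Six3. Among genes of other lineages Tbx4 and Runx1 had 5 each and Ptprc had 6. Notch1, Lhx4, Six3 and Runx1 were marked at another annotated start, whereas Otx2, Sox14, Tbx4 and Ptprc were marked at none, and distance was measured from the 5' end alone. These genes were chosen after their values were seen.

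The hypothesis that distal peaks carry binding sequences of neural factors was tested with 6-base words in 13484 distal peaks and their flanks, with bounds written before the results were seen. The E-box CAGCTG, bound by proneural and other factors, had a log2 ratio of 0.56 ± 0.03 (jackknife SE over 21 chromosomes), above the median of 0.05 of its 41 control words of the same composition, of which 3 were as high. This is consistent with E-box enrichment, but the word ranked only 13 of 1268 words, and GCTGCA and AGCTGC, which share GCTG with it, ranked higher. A broader preference for such sequence is therefore a possible explanation. The SOX-type words were less frequent in peaks than in flanks (-0.11 ± 0.02), above their control median of -0.31, and 20 of their 123 control words were as high. The homeodomain word TAATTA had -0.11 ± 0.03, and none of its 13 control words, with a median of -0.59, was as high. Both fell below the bound set beforehand, but that bound took no account of base composition, as the control medians showed afterwards, so neither test decided anything. GATAAG, named beforehand as the negative control, had -0.38 ± 0.03 against a control median of -0.34, with 35 of 59 control words as high. It is a GATA-type word, and Gata2 and Gata3 were among the marked spinal neuron factors, so it is not a strict negative control in this tissue.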
